A study of Rattus norvegicus with 141 samples.

How the data were processed

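RNA was measured in 141 libraries of rat PC12 cells, 47 groups of 3, after treatment with 14 extracts at 20, 100 and 500 µg/mL or with 4 reference drugs, and in non-treated cells. Libraries were made with a directional mRNA kit, per the labels. The files hold the expected count per gene and transcript that the authors deposited, made with RSEM 1.3.3 per the submitters' processing notes, and 93.7% of the gene values are whole numbers. The genome build and the annotation release are not given in the sources used here. Each file gives genes by Ensembl rat identifiers with version numbers. The reference table holds symbols without Ensembl identifiers, so 0 of 32883 identifiers matched a symbol, and the gene lists and the rule for named genes, both fixed before the data were examined and both needing symbols, were not applied. Values are given for 4 genes by identifier, chosen after their values were seen.

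Groups, extracts and doses come from the sample titles. Library names give a set (9 sets), a replicate and a position in the set. Each group lies in 1 set, so the set cannot be a term in the model. No pair of libraries held identical values (0 pairs), and within groups the chi-square per degree of freedom between counts of 2 libraries ran from 2.42 to 241.9, so that no libraries were merged. Total counts ran from 5399412 to 31918020 per library.

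Expected counts were rounded to whole numbers, scaled with TMM factors, filtered with edgeR's filterByExpr on group (13891 genes kept), and tested with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood F test, in 1 fit with a mean for each of the 47 groups and no replicate block. Genes were called at a Benjamini-Hochberg adjusted p of 0.05 within each comparison, and at least 2-fold changes were counted among them. The 24 comparisons of the design and the 42 groups against non-treated cells use this fit. Contrasts over several extracts take the mean of the extracts and treat them as fixed, so they describe these extracts. CPM values use the TMM-scaled library sizes, and SDs are over 3 libraries. Gene groups were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 between genes and with an estimated one, adjusted over all 56 tests. They use genes called in 1 comparison and contrasts that share no library with it. Similarity of responses is the Pearson correlation across genes of log2 fold changes between contrasts that share no library.

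Settings varied, chosen before the data were examined, were the size factors of DESeq2 in the edgeR fit, the Wald test of DESeq2 1.42.0, no filter on low counts, a fit to the groups compared alone, the replicate number as a block (over all sets and within each set), leaving out replicates, and for similarity and gene groups genes with a mean of at least 10 CPM and an estimated correlation. Chosen after seeing the data were the fits without replicate 3 of JGE02 at 500 µg/mL, the fits with a batch term, the differences between solvents, herbs, extraction orders and mixtures at 20 µg/mL and their change from 20 to 500 µg/mL, the dose effect of single extracts, the comparison of 100 µg/mL with the other doses, the solvent difference over all extracts at each dose, and the gene groups. The batch term parts library sets 1 to 5 and replicate 1 of set 6 (84 libraries) from replicates 2 and 3 of set 6 and sets 7 to 9 (57 libraries). The split was seen in the principal components and follows library numbers. The early batch holds 6 ethanol libraries, on which the separation of batch from solvent rests.

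The steps were tested on simulated counts with 200 changed genes per comparison among 13818 genes. For duloxetine edgeR recovered 66 of 100 genes changed 1.5-fold and 86 of 100 changed 2-fold, with 4 false calls. For the ethanol dose comparison it recovered 78 of 100 changed 1.2-fold and 96 of 100 changed 1.5-fold, with 9 false calls. With no changed genes, aspirin and the water dose comparison gave 0 calls. The simulated counts held no differences between library sets, batches or positions, so these 0 calls do not speak of such differences. Their spread came from the fit with all libraries, the doubtful JGE02 library included. DESeq2 on 6 libraries recovered 63 and 80 of 100 for duloxetine, with 30 false calls.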

Results

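The series measured the transcriptome of PC12 cells, a rat pheochromocytoma line that takes on a neuron-like form when treated with nerve growth factor. The differentiated cells received extracts of Jakyakgamcho-tang (JGT), a traditional East Asian preparation of 2 herbs, peony root (Jakyak, here PR) and licorice (Gamcho, here GR). There were 141 RNA-seq libraries in 47 groups of 3. Of these 1 group was non-treated, and 4 groups received a reference drug each: amifostine (a cytoprotective thiol prodrug), resveratrol (a plant polyphenol), duloxetine (a serotonin and noradrenaline reuptake inhibitor) or aspirin (a cyclooxygenase inhibitor). The other 42 groups were 14 extracts, each at 20, 100 and 500 µg/mL. Of the 14 extracts 7 were made with hot water (JGW) and 7 with 70% ethanol (JGE), and within each solvent the number 01 was PR alone, 05 was GR alone, 02 and 04 were JGT mixed and then extracted, and 06, 07 and 08 were JGT extracted and then mixed. The labels do not say which mixture has which herb ratio, so ratios were not compared, and they give no drug dose, treatment time or vehicle. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

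Total expected counts per library ran from 5399412 to 31918020, with a median of 23311007. The lowest total belonged to replicate 3 of JGE02 at 500 µg/mL, and the next lowest library had 16755151. The library with the lowest total had a mean fragment length of 162 bases, against 233 to 235 bases in its partners, and lay 1.39 log2 units (root mean square over genes) from the mean of its partners, where the median library lay 0.335 away. Of the 32883 genes in the files 13891 had enough counts to be tested. The biological coefficient of variation was 0.0877 with this library and 0.0682 without it, and for this reason the main counts of changed genes are given below with all libraries first and then without this one. The files give Ensembl rat gene identifiers without symbols, and 0 of them could be paired with a symbol, so results are reported as counts of genes, as gene groups defined by their response, and for 4 identified genes.

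**Figure D1:**
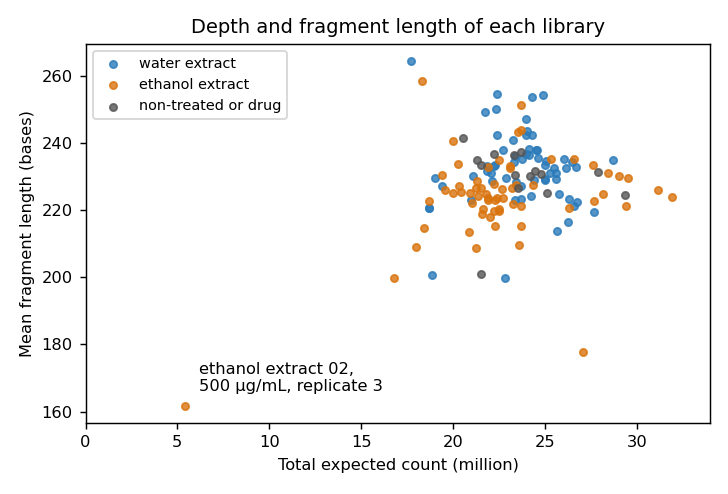
Total expected count of each library (x axis, in the unit given on the axis) against its mean fragment length in bases (y axis). Each point is 1 library, coloured by water extract, ethanol extract, or non-treated and drug groups. Replicate 3 of JGE02 at 500 µg/mL, at 5399412 counts and 162 bases, lies away from the other libraries.

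The first principal component of the expression values, calculated without that library, took 7.69% of the variance and set most ethanol-extract libraries apart from the rest, at all 3 doses. Library names place the non-treated and drug libraries in set 1, the water extracts in sets 2 to 5 and the ethanol extracts in sets 6 to 9, so that set explained 74.3% of this component. The division did not follow the solvent fully. All 6 libraries of replicate 1 in set 6, which hold the ethanol extracts JGE01 and JGE02 at 3 doses, lay with the water extracts. On 4100 genes that differed between solvents at 100 µg/mL in the extracts numbered 04 to 08, which excludes set 6, these 6 libraries had a mean score of -0.0539 log2 units. The 6 libraries of replicate 2 in the same groups scored 0.0593, and the water extracts between -0.197 and 0.0291. A second library, replicate 3 of JGE02 at 100 µg/mL, also scored with the water extracts, at -0.0784. Libraries before and after this division are treated as 2 batches of 84 and 57 libraries. Replicate 3 of JGE02 at 100 µg/mL is placed in the late batch by its library number, against its score. Comparisons between solvents and of ethanol extracts with non-treated cells are given also from a fit with a batch term, chosen after seeing the data.

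**Figure D2:**
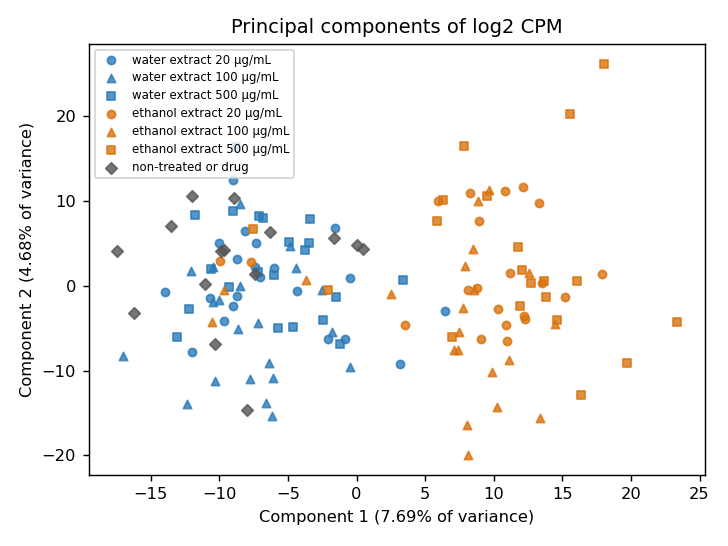
First and second principal components of log2 CPM for all libraries but replicate 3 of JGE02 at 500 µg/mL, with the share of variance on each axis. Colour gives the kind of treatment and shape the dose. Most ethanol-extract libraries (orange) lie to the right at every dose, while the 6 of replicate 1 in library set 6 lie to the left with the water extracts.

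Duloxetine changed more genes than any other reference drug. Against non-treated cells 1859 genes were higher and 1862 lower after duloxetine, and 205 of these 3721 genes differed at least 2-fold. Resveratrol raised 470 genes and lowered 540, with 56 differing at least 2-fold. Amifostine raised 197 and lowered 261, with 19 differing at least 2-fold. Aspirin raised 8 genes and lowered 13. The median absolute change of called genes was 0.36 log2 units for duloxetine and for resveratrol and 0.32 for amifostine. These are edgeR quasi-likelihood tests at an adjusted p of 0.05, 3 libraries against 3 in the same library set. Without the doubtful JGE02 library the totals were 4893 for duloxetine, 1839 for resveratrol, 1032 for amifostine and 119 for aspirin. Without non-treated replicate 1 they were 2884, 421, 184 and 0, with 48 for aspirin by DESeq2 on all libraries, and without non-treated replicate 3 amifostine had 273 and aspirin 2.

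The extracts were then compared with non-treated cells, at the highest dose first. Among water extracts at 500 µg/mL, PR raised 19 genes and lowered 9, GR raised 96 and lowered 93, and the 5 JGT mixtures together raised 501 and lowered 615. Among ethanol extracts at 500 µg/mL, PR raised 1394 genes and lowered 1513, GR raised 1279 and lowered 1223, and the 5 mixtures together raised 1889 and lowered 1979. PR and GR were tested with 3 libraries against 3 and the mixtures with 15 against 3, so herbs and mixtures cannot be ranked by these counts. At least 2-fold changes numbered 201 for ethanol PR and 137 for ethanol GR, against 2 and 7 for water PR and GR (4 and 15 without the doubtful library). Leaving out the doubtful library gave totals of 103, 446 and 2092 for water PR, GR and JGT, and 4122, 3659 and 4512 for the ethanol extracts in the same order. With the batch term the ethanol totals were 2451, 2361 and 2635, and 3369, 3417 and 4037 when the doubtful library was also left out. A fit to the groups compared alone, with all libraries, called 441 genes for ethanol JGT and 2015 for water JGT. Extracts and non-treated cells lie in different library sets, and the set and the treatment cannot be told apart in these comparisons. Leaving out non-treated replicate 1 gave 10, 89 and 263 genes for water PR, GR and JGT and 2237 for ethanol JGT, and leaving out non-treated replicate 3 gave 9, 82 and 577 for the water extracts.

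At the lowest dose the mean of the 14 extracts still differed from non-treated cells, by 587 higher and 749 lower genes. The total was 2524 without the doubtful library, 1281 with the batch term, 2274 with both changes, 312 without non-treated replicate 1 and 498 without non-treated replicate 3. Over the 42 extract and dose groups the median number of genes that differed from non-treated cells was 437, and 1130 without the doubtful library. The number did not follow the dose in order. It was highest at 500 µg/mL for 13 of 14 extracts, but for 11 of 14 extracts it was higher at 20 than at 100 µg/mL. All 14 extracts are compared with the same non-treated libraries, so these are not 14 separate observations. Dose also goes with library position within each extract. For JGE07 the counts were 1937 at 20, 892 at 100 and 4695 at 500 µg/mL, with 3205, 1925 and 5912 without the doubtful library, 1662, 997 and 4153 with the batch term, and 2840, 1853 and 5589 with both changes. With the batch term and all libraries the order of 20 and 100 µg/mL turned in 3 extracts, to 432 and 788 in JGE02, 961 and 978 in JGE05, and 514 and 525 in JGE06. With the batch term and without the doubtful library it turned in JGE02 (940 and 1591) but not in JGE05 (1769 and 1636) or JGE06 (1065 and 1057). It also turned there in JGE04, to 1392 and 1842, from 2132 and 2115 without the term. In both batch fits the count of JGE02 at 100 µg/mL includes replicate 3, which the term places in the late batch against its score.

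The comparison of 500 with 20 µg/mL lies within a library set and does not use the non-treated cells. Ethanol extracts changed many more genes with dose than water extracts. Over the 7 ethanol extracts 1783 genes rose from 20 to 500 µg/mL and 1692 fell, and over the 7 water extracts 213 rose and 108 fell. Among called genes the median absolute change was 0.14 log2 units in ethanol and 0.15 in water. A direct test of the difference between solvents in the dose effect called 739 genes, 240 more positive and 499 more negative in ethanol. Without the doubtful library the totals were 3790 for ethanol, 579 for water and 1014 for the difference, and a fit to the groups compared alone called 1687 in ethanol and 597 in water. Within each extract the dose goes with the position of the library in its set, so dose and position cannot be told apart within a solvent. The positions are the same in both solvents. A position effect common to all sets would cancel in the difference between solvents, so the 739 genes argue against it as the cause of that difference.

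By single extracts the dose effect was uneven. In ethanol, PR (JGE01) raised 696 genes and lowered 925 between 20 and 500 µg/mL, and GR (JGE05) raised 254 and lowered 235. Among the ethanol mixtures JGE07 raised 370 and lowered 1123, JGE04 raised 167 and lowered 168, JGE06 raised 143 and lowered 239, and JGE08 raised 1 and lowered 0, with 2 and 1 without the doubtful library. JGE02 raised 2448 and lowered 1338, but without its doubtful replicate it raised 67 and lowered 101. Each of the 7 water extracts raised between 1 and 8 genes and lowered 0, in edgeR with 3 libraries against 3. Without the doubtful library JGE01 raised 1116 and lowered 1322, JGE05 raised 471 and lowered 431, JGE07 raised 903 and lowered 1632, JGE04 raised 361 and lowered 360, JGE06 raised 276 and lowered 382, water GR (JGW05) raised 19 and lowered 5, JGW04 raised 12 and lowered 0, and JGW08 raised 6 and lowered 0.

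**Figure D3:**
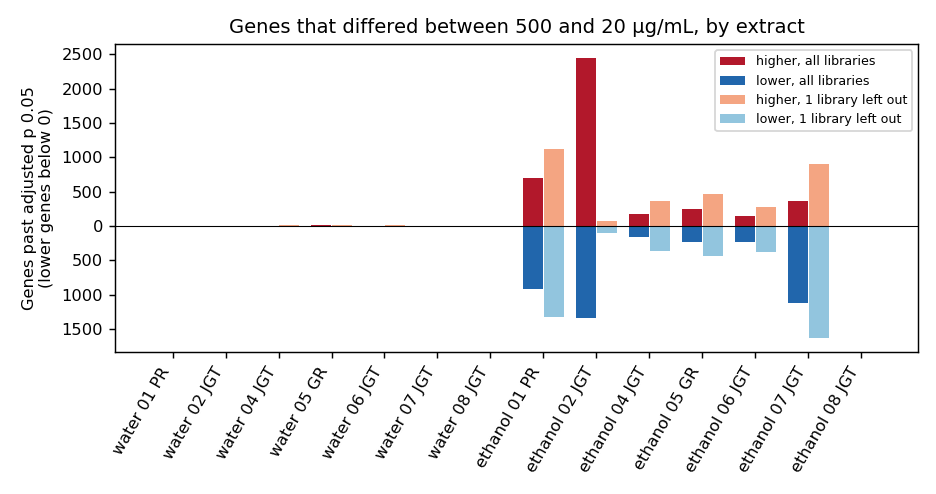
Number of genes past an adjusted p of 0.05 between 500 and 20 µg/mL for each extract, with genes higher at 500 above 0 and genes lower at 500 below 0. Dark bars use all libraries and light bars leave out replicate 3 of JGE02 at 500 µg/mL. The bars of JGE02 go from 2448 and 1338 to 67 and 101 when that library is left out, and the water extracts have at most 19 higher genes in either count.

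The dose response is given in full for 4 genes, chosen after their values were seen, which passed the threshold in many of the 14 extracts taken singly. ENSRNOG00000014117.7 rose between 20 and 500 µg/mL in 7 of 7 water and 6 of 7 ethanol extracts, and its estimate was positive in all 14. In ethanol GR it went from 850 ± 82.1 to 1567 ± 33.2 CPM (SD, n = 3), a log2 change of 0.88 (adjusted p = 2.95e-17), and in ethanol PR from 905 ± 29.5 to 1061 ± 38 CPM. In non-treated cells it was at 895 ± 38.8 CPM, in duloxetine at 1934 ± 138 CPM, in resveratrol at 1327 ± 16.5 CPM and in amifostine at 689 ± 20.4 CPM, and these 3 drug differences passed the test. ENSRNOG00000028812.5 rose in 6 of 7 water and 6 of 7 ethanol extracts. It went from 14.6 ± 1.22 to 31.2 ± 2.14 CPM in ethanol GR (log2 change 1.10, adjusted p = 3.27e-16) and stood at 15.02 ± 1.55 and 15.1 ± 1.65 CPM in ethanol PR (log2 change 0.01, adjusted p = 0.971). Amifostine lowered it, to 7.79 ± 1.15 CPM against 14.9 ± 0.681 CPM in non-treated cells.

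ENSRNOG00000024825.5 fell between 20 and 500 µg/mL in 6 of 7 ethanol extracts and in 0 of 7 water extracts taken singly, with a negative estimate in all 14. Without the doubtful library it also passed in water GR (adjusted p = 0.00558, from 0.307), as did ENSRNOG00000016311.7 (adjusted p = 0.0121, from 0.0801). It went from 193 ± 2.61 to 132 ± 3.64 CPM in ethanol PR and from 189 ± 3.23 to 129 ± 1.76 CPM in ethanol GR. Over the 7 ethanol extracts it fell by 0.46 on the log2 scale (SE 0.024) and over the 7 water extracts by 0.14 (SE 0.024), and the difference passed the test (adjusted p = 4.89e-12). Duloxetine lowered it to 123 ± 9.69 CPM from 188 ± 5.93 CPM in non-treated cells. ENSRNOG00000016311.7 fell in the same number of extracts, from 117 ± 8.73 to 59.3 ± 3.48 CPM in ethanol GR, and duloxetine lowered it to 74.3 ± 6.12 CPM from 151 ± 16 CPM. The pooled fall was 0.54 on the log2 scale in ethanol and 0.31 in water (adjusted p of the difference 0.00139).

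**Figure D4:**
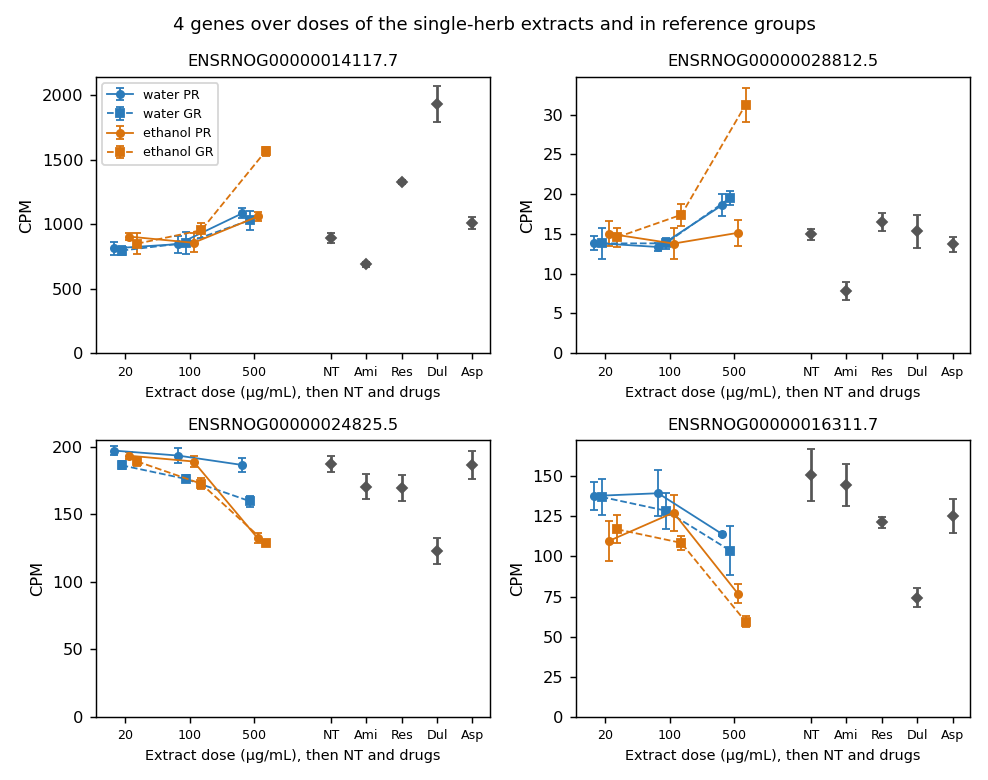
Mean CPM (y axis, error bars SD, n = 3) of 4 genes at 20, 100 and 500 µg/mL of the single-herb extracts, followed by non-treated cells and the drugs. Blue is water and orange ethanol, circles with solid lines are PR and squares with dashed lines GR, and grey diamonds are non-treated (NT), amifostine, resveratrol, duloxetine and aspirin. In the upper right panel ethanol GR reaches 31.2 CPM at 500 µg/mL while ethanol PR stays at 15.1 CPM.

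Genes that responded to dose in 1 ethanol extract were followed in extracts that share no library with it. Dose goes with library position in every extract, so an effect of position could also carry a gene group from 1 extract to another. This set of tests was chosen after seeing the data, in place of the pathway lists, which need symbols. Of the 254 genes that rose in ethanol GR, 8 rose in water GR in the test over all genes (18 without the doubtful library) and 44 when adjusted over the list alone, 0 fell, and the group's median change was 0.13 log2 units (camera, adjusted p = 3.72e-18 with an estimated correlation). In water JGT 62 of the 254 rose and 0 fell, and in ethanol JGT 152 rose and 3 fell. Of the 235 genes that fell in ethanol GR, 0 fell in water GR over all genes in edgeR (4 without the doubtful library) and 8 over the list alone, while 32 fell in water JGT and 146 in ethanol JGT, and the group's camera test passed in all 3.

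The genes of the ethanol PR response were followed in the same way. Of the 696 genes that rose in ethanol PR, 233 rose and 2 fell in ethanol JGT, and of the 925 that fell, 467 fell and 8 rose there. In water PR the group of 696 had a median change of 0.02 log2 units, with 1 gene higher and 0 lower (camera, adjusted p = 0.0419 with the preset correlation and adjusted p = 0.472 with an estimated correlation). The group of 925 had a median of -0.01 in water PR, with 0 genes called in edgeR over all genes and 0 over the list alone (adjusted p = 0.837 with an estimated correlation). In ethanol GR 34 of the 696 rose and 11 fell (48 and 28 without the doubtful library), and 62 of the 925 fell and 35 rose (93 and 54), and neither group passed the camera test (adjusted p = 0.781 for both with an estimated correlation). In the reverse direction, of the 235 genes that fell in ethanol GR 62 fell and 11 rose in ethanol PR (adjusted p = 0.00943 with an estimated correlation), and of the 254 that rose 34 rose and 35 fell (adjusted p = 0.987 with an estimated correlation).

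The response to duloxetine, measured in library set 1, overlapped in direction with that to ethanol GR. Of the 1859 genes raised by duloxetine 123 rose and 3 fell in ethanol GR between 20 and 500 µg/mL, and of the 1862 lowered by it 169 fell and 22 rose (adjusted p = 0.00943 and 0.0046 with an estimated correlation). The median changes were 0.05 and -0.07 log2 units. Leaving out the doubtful library gave 199 and 6 genes of the first group and 271 and 35 of the second. In ethanol PR 149 of the 1859 genes rose and 139 fell, and of the 1862 genes 87 rose and 256 fell, with a median of -0.04 log2 units (adjusted p = 0.00666 with the preset correlation and adjusted p = 0.46 with an estimated correlation). In ethanol JGT 315 of the 1859 genes rose and 104 fell, and 476 of the 1862 fell and 120 rose, which passed with the preset correlation and not with the estimated one (adjusted p = 0.368 and adjusted p = 0.0676 with an estimated correlation). In the 3 water classes neither duloxetine group passed with an estimated correlation. Of 56 such tests of gene groups 29 passed with a preset correlation of 0.01 and 12 with an estimated one.

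**Figure D5:**
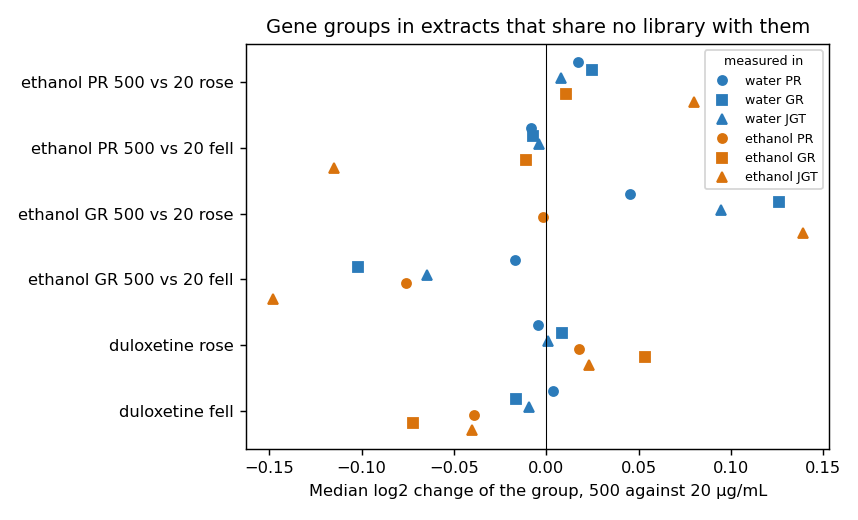
Median log2 change from 20 to 500 µg/mL (x axis) of 6 gene groups (rows), each defined by a response to duloxetine, ethanol PR or ethanol GR, in extract classes that share no library with the definition. Blue is water and orange ethanol, circles are PR, squares GR and triangles JGT. The group that rose in ethanol GR lies at 0.13 in water GR, and the group that rose in ethanol PR lies at 0.02 in water PR.

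Across all 13891 genes the dose effects of the 7 water and the 7 ethanol extracts had a Pearson correlation of 0.163, and those of ethanol PR and ethanol GR of 0.0059. These are correlations across genes, which are not independent replicates. The first ran from 0.0275 to 0.388 over the settings tried, and its rank correlation was 0.325. The dose effect of the mixture JGE04 had a correlation of 0.366 with that of ethanol GR and -0.0995 with that of ethanol PR (rank correlations 0.522 and 0.0366). The mixture JGE06 had 0.226 with ethanol PR and -0.104 with ethanol GR (rank correlations 0.509 and 0.139). Differences between these correlations were not tested.

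The solvents were compared at 500 µg/mL for each class of extract. PR and GR were each tested with 3 libraries against 3 and the mixtures with 15 against 15. Counts for the herbs and the mixtures therefore cannot be ranked against each other. Ethanol PR had 875 genes higher and 1104 lower than water PR, ethanol GR had 369 higher and 332 lower than water GR, and the ethanol mixtures had 2127 higher and 2049 lower than the water mixtures. At 20 µg/mL the same comparisons gave 12 genes for PR, 7 for GR and 1280 for the mixtures, with 39, 116 and 2442 without the doubtful library and 46, 24 and 978 with the batch term (165, 173 and 1538 with the batch term and without that library). Of the 1538 genes for the mixtures 429 were among the 2442 called without the term. At 20 µg/mL, without the term and with all libraries, 1030, 1230 and 3249 genes were at an unadjusted p under 0.05, in the same order. The difference between the 2 doses, in which offsets between library sets cancel, called 553 genes for PR, 8 for GR and 240 for the mixtures. These were 979, 24 and 344 when the doubtful library was left out. The contrasts at 500 µg/mL cross the batches, and with the batch term they gave 1953, 636 and 1644 genes, or 2819, 1292 and 2797 with the batch term and without the doubtful library. They gave 2998 for PR, 1580 for GR and 4078 for the mixtures without the doubtful library and without the batch term. Of these 2137, 679 and 1427 were also called with the batch term on the same libraries, so the term changed which genes were called. A fit to the groups compared alone, with all libraries, gave 355 for GR and 1171 for the mixtures.

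The 2 herbs differed in ethanol. PR and GR lie in different library sets (2 and 4 in water, 6 and 8 in ethanol), so herb and set cannot be told apart at a single dose. At 500 µg/mL ethanol GR had 1408 genes higher and 1281 lower than ethanol PR, 186 of them by at least 2-fold. At 20 µg/mL it had 0 higher and 0 lower (edgeR, 595 genes at an unadjusted p under 0.05, and 7 past the threshold without the doubtful library), and the difference between doses called 1045 genes, 618 more positive and 427 more negative in GR. In water, GR had 8 genes higher and 5 lower than PR, and the difference between doses called 0 genes, with 308 at an unadjusted p under 0.05 in edgeR and 1 gene past the threshold without the doubtful library. A test of whether the herb difference at 500 µg/mL depends on the solvent called 798 genes. Without the doubtful library the counts were 3843 in ethanol, 57 in water, 1674 for the dose difference in ethanol and 1403 for the dependence on solvent. Replicate 1 of ethanol PR lies in the early batch and ethanol GR in the late one. With the batch term the ethanol counts were 3023 at 500 µg/mL, 6 at 20 µg/mL and 1121 for the dose difference. They were 4247, 36 and 1778 when the doubtful library was also left out. DESeq2 called 38 genes between the herbs in water.

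Extraction before or after mixing was compared with 3 extracts (06, 07 and 08) against 2 (02 and 04), so the test describes these 5 extracts. In both solvents the orders lie in different library sets (2 and 3 against 4 and 5 in water, 6 and 7 against 8 and 9 in ethanol), so order and set cannot be told apart at a single dose. In water at 500 µg/mL 9 genes were higher and 13 lower in extracts mixed after extraction, with 36 genes at 20 µg/mL (194 without the doubtful library) and 0 for the difference between doses (edgeR, 198 at an unadjusted p under 0.05, and 0 without the doubtful library). In ethanol 1122 were higher and 1980 lower, with 0 at 20 µg/mL (edgeR, 1049 at an unadjusted p under 0.05, and 29 past the threshold without the doubtful library) and 612 for the difference between doses. The ethanol difference included JGE02 at 500 µg/mL. Without its doubtful replicate 724 genes were higher and 1008 lower, and the difference between doses called 28 genes in place of 612. The water count was 107 without that library. In a fit to the 5 ethanol groups alone 1 gene passed.

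The mixtures were compared with the mean of the 2 herbs at 500 µg/mL. In water 0 genes passed in edgeR, with or without the doubtful library, 807 were at an unadjusted p under 0.05, and DESeq2 called 6. In ethanol 410 genes were higher and 328 lower in the mixtures, at 20 µg/mL 0 genes passed (edgeR, 355 at an unadjusted p under 0.05), and the difference between doses called 32 genes, 28 of them more positive in the mixtures. These were 856 and 84 genes without the doubtful library. A fit to the 7 groups alone called 13.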

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

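Tests of this part chosen only after the result was seen were those of the library batch, of an exchange of libraries, of the library position, of the change with dose of the differences between solvents, herbs, extraction orders and mixtures, of 100 µg/mL against the other doses, of ethanol against water over all extracts, the choice of the 4 genes, and all fits without replicate 3 of JGE02 at 500 µg/mL. What the position test could decide was also settled after its values were seen. The test of a wrong label was narrowed to other groups of the series, and the spread over extracts was used for the solvent ratio, after their values were seen. An earlier explanation, a constant offset between library sets, was to be read from the same solvent ratio, which could not decide it, and the batch test took its place.

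The following results stood out because an effect differed between groups by a test of the difference. The dose effect differed between solvents in 739 genes. The herb difference at 500 µg/mL differed between solvents in 798 genes. The ethanol minus water difference changed from 20 to 500 µg/mL in 553 genes for PR, 8 for GR and 240 for the mixtures. The GR minus PR difference in ethanol changed with dose in 1045 genes. The difference by extraction order in ethanol changed with dose in 612 genes, and in 28 without the doubtful JGE02 library. The difference between mixtures and single herbs in ethanol changed with dose in 32 genes. The dose effect in ethanol minus that in water was -0.3136 log2 units for ENSRNOG00000024825.5 and -0.2284 for ENSRNOG00000016311.7. The GR minus PR difference at 500 µg/mL was larger in ethanol than in water by 0.6343 log2 units for ENSRNOG00000014117.7 and by 0.9754 for ENSRNOG00000028812.5.

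Replicate 3 of JGE02 at 500 µg/mL stood 1.39 log2 units from its partners. A partner thinned to its depth of 5399412 counts lay on average 0.4911 from the other partner (0.486 to 0.498 over 5 draws of each). At full depth the partners lay 0.418 apart. These distances are to 1 library, while the 1.39 is to the mean of 2 partners. The values argue against depth alone. Removing a trend on gene length left a distance of 1.382, which argues against such a trend. Its nearest other group, JGE07 at 500 µg/mL, lay at 1.352, nearer than its own partners. The highest distance of a library outside this group to its own partners was 0.463, so an ordinary library taken from another group of the series is not supported. A library of low quality could lie far from every group, its true one included, so the test cannot decide on a wrong label for such a library. RNA quality and a sample from outside the series stay open, and no biological explanation was tested.

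Ethanol and water extracts differed at 20 µg/mL already, in 2482 genes, and in 3848 without the doubtful library, and at 500 µg/mL they differed in 5344 and 5763. The median difference at 500 was 1.151 times that at 20 µg/mL (1.11 to 1.21 when 1 extract was left out), under the bound set before the ratio was seen, which argues against a growing solvent effect as the whole cause for the genes called at 100 µg/mL, while the difference did change with dose in the 553 genes for PR and 240 for the mixtures given above. The 6 ethanol libraries of replicate 1 in set 6 had a mean score of -0.0539, below all 6 of replicate 2 (0.0343 to 0.0994). They scored from -0.0754 to -0.0295, within the range of the water extracts (-0.197 to 0.0291). On the 4100 genes of this score a library batch that changed within set 6 may thus account for the difference. Barring an exchange of libraries, the scores argue against a solvent effect constant over dose in JGE01 and JGE02 on these genes. For ethanol PR at 20 and 500 µg/mL an exchange with water libraries in replicate 1 is argued against. The ethanol PR change in replicate 1 correlated at 0.79 across 9099 genes with that in replicates 2 and 3, and at 0.0752 with water PR. The JGE02 libraries and ethanol PR at 100 µg/mL in that replicate were not tested for an exchange. With the batch term 1382 genes differed at 20 µg/mL (1908 without the doubtful library), a separation that rests on 6 libraries. Of the 1908 genes 758 were among the 3848 called without the term, so the term changed which genes were called. A solvent effect constant over dose stays open for other genes and extracts.

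Extracts at 100 µg/mL differed from the mean of 20 and 500 µg/mL in 3124 genes, and in 4007 without the doubtful library. With fragment length and depth as covariates 4103 genes were called, although 1774 genes followed fragment length within groups, which argues against these as the whole cause. Library position goes with dose within extracts. Duloxetine, at a middle position, scored -0.0437 (SE 0.0162) against the other 3 drugs on these genes, opposite to what position would give, and non-treated cells scored 0.107, but drug effects on the same genes enter both scores, so position and dose cannot be told apart. A response to dose that is not monotonic also stays open, as untested.

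Other splits of the same libraries were tested with limma on log2 CPM. They move single libraries, so they speak of chance among libraries and not of differences between extracts or library sets. For 12 comparisons of 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and 1 of 10, the real one, gave as many genes in each. The real count and the highest other were 304 and 3 for amifostine, 1035 and 3 for resveratrol, 4260 and 1 for duloxetine, 3 and 2 for aspirin, 6 and 2 for water PR, 58 and 2 for water GR, 2405 and 3 for ethanol PR, 2028 and 2 for ethanol GR, 1288 and 2 for ethanol against water PR, 155 and 1 for ethanol against water GR, 4 and 1 for GR against PR in water, and 1509 and 2 in ethanol. Of 100 splits 1 gave as many genes for water JGT against non-treated (1609, highest other 359) and all extracts at 20 µg/mL (1888 and 61). The same held for the ethanol dose effect (1079 and 0), the dose effect by solvent (198 and 0) and ethanol against water JGT (785 and 0). These counts argue against a chance division of single libraries. For the water extraction order 1 of 100 also did (8 and 3). There 8 lies near 3, and the edgeR count fell to 0 in a fit with replicates left out, so chance is not excluded. The edgeR count of 107 came from leaving out the doubtful library, which is in no water group. The orders also lie in different library sets, so set and order cannot be told apart. For the water dose effect 2 of 100 gave as many genes (465 and 701). The split with 701 put 8 and 4 libraries of set 2 and 4 and 8 of set 4 on its sides, which follows library sets in part. For ethanol JGT against non-treated 4 of 100 did (157 and 3948), and without the doubtful library 3 of 100 (1878 and 2522), and a split that calls many times the real count points to a structure of the samples. For the herb effect by solvent 8 of 100 did (609 and 1268), a share that is not under 0.05. All 7 others kept the ethanol labels and so the real ethanol difference between herbs, and the highest count among splits with the ethanol labels mixed was 1, so the share does not speak for chance in the ethanol libraries. For the ethanol extraction order (0 and 2) and for mixtures against single herbs in water (0 and 1) and in ethanol (0 and 1) the real count was 0, which 100 of 100 splits reach whatever the data, so these splits decide nothing there. Without the doubtful library the ethanol extraction order gave 2 genes, with 3 of 100 splits as large and a highest other of 469.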

How the results depend on the processing

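The fits without the doubtful JGE02 library and those with a batch term were chosen after seeing the data, and the other settings before the data were examined. With the size factors of DESeq2 each count stayed within 1.5 times. All 112 checks of the dose effects of the 4 genes over the 7 water and the 7 ethanol extracts kept the call (single extracts were not among these). These genes were chosen from the same libraries for passing in the most extracts, so the checks say nothing of other genes. The gene lists were not run, since no symbols could be matched. The cause of the shifts below was not tested. Replicate numbers were not treated as pairs, since the correlation of deviations between libraries of the same number and set was over 0.1 in 102 of 318 pairs, not in all. Its mean was 0.0652, against 0.00967 for the same number in other sets, so a pairing within sets is not excluded. In set 6 replicate 1 stood apart as described. The mean of -0.0326 for other numbers of the same set follows from the use of deviations from group means, so it adds no comparison. With the replicate block the counts moved by over 1.5 times to 34 for aspirin, 58 for water PR, 45 for GR against PR in water and 41 for the water order. With a replicate block within library set they were 956 for amifostine, 1675 for resveratrol, 249 for aspirin, 205, 519 and 1829 for water PR, GR and JGT, 2089 for all extracts at 20 µg/mL, 557 for the water dose effect, 1167 for dose by solvent, 1270 for ethanol against water GR, 150 for GR against PR in water, 1242 for herb by solvent, 198 for the water order, and 34 and 1394 for mixtures against single herbs in water and ethanol. This block raised every count that was above 0, to 1.15 to 11.9 times the main count. No filter on low counts gave 304 for amifostine, 6 for aspirin, 123 for water GR, 450 for ethanol against water GR, 7 for GR against PR in water, 13 for the water order and 434 for mixtures against single herbs in ethanol. A fit to the groups compared alone gave 1554 for resveratrol, 94 for aspirin, 2015 for water JGT, 441 for ethanol JGT, 2816 for all extracts at 20 µg/mL, 597 and 1687 for the dose effect in water and ethanol, 355 and 1171 for ethanol against water GR and JGT, 22 and 1735 for GR against PR in water and ethanol, 80 and 1 for the order in water and ethanol, and 13 for mixtures against single herbs in ethanol. The DESeq2 test gave 48 for aspirin, 54 for water PR, 38 for GR against PR in water, 35 for the water order and 6 for mixtures against single herbs in water. With the batch term the counts were 45 for water PR, 23 for GR against PR in water, 38 for the water order and 1644 for ethanol against water JGT, and 157, 91, 158 and 2797 when the doubtful library was also left out. The correlation of the water and ethanol dose effects was 0.0531 with no filter, 0.0533 in DESeq2 and 0.388 over genes with a mean of at least 10 CPM. Of 56 gene group tests 12 passed with an estimated correlation.

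The counts below are ranges over fits with replicates, or the doubtful JGE02 library alone, left out. They ran from 86 to 1032 for amifostine, 180 to 1839 for resveratrol, 2161 to 4893 for duloxetine and 0 to 119 for aspirin. Against non-treated cells they ran from 3 to 103 for water PR, 31 to 446 for water GR, 177 to 2092 for water JGT, 1719 to 4122 for ethanol PR, 1151 to 3659 for ethanol GR, 1962 to 4751 for ethanol JGT and 225 to 2602 for all extracts at 20 µg/mL. The dose effect ran from 108 to 579 in water and 2137 to 3790 in ethanol, and dose by solvent from 272 to 1034. Ethanol against water ran from 899 to 2998 for PR, 81 to 1580 for GR and 2678 to 4078 for JGT. GR against PR ran from 0 to 57 in water and 1325 to 3843 in ethanol, and herb by solvent from 324 to 1403. The order ran from 0 to 107 in water and 1732 to 3908 in ethanol, and mixtures against single herbs from 0 to 9 in water and 85 to 1391 in ethanol. The doubtful library is in none of the drug or water comparisons and acts on them only through the shared fit. Leaving it out gave the upper ends for the drugs and for water PR, GR and JGT against non-treated cells. It also gave those for the water dose effect and, in water, for GR against PR and the order. The similarity ran from 0.0275 to 0.264. Without the doubtful library the median over 42 groups was 1130 and 27 gene group tests passed. In the simulated comparison of 3 libraries against 3, 66 of 100 genes changed 1.5-fold were recovered, so at this depth and spread a gene that was not called is not shown to be unchanged.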

Other observations

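The tests in this part, of gene groups, of single extracts and of the licorice and peony responses, were chosen after the data were examined. Calls were shared among ethanol extracts more often than independent lists would give if every gene had the same chance of a call. Between 20 and 500 µg/mL 155 genes rose in at least 3 of the 7 ethanol extracts, where independent lists of the same sizes give 12.8, and 307 fell in at least 3, where they give 20.6. These counts include JGE02 with its doubtful library, and no count without it was made. Genes differ in expression and spread, and so in their chance of a call in any extract. The excess alone therefore does not show a shared response. In water 12 genes rose in at least 1 extract and 2 rose in at least 6 of 7.

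Correlations of the other ethanol mixtures with the herbs are given as values, and differences between them were not tested. The dose effect of JGE02 correlated across genes at 0.0146 with ethanol PR and 0.22 with ethanol GR on all libraries, and at 0.186 and 0.0728 without its replicate 3. For JGE07 the correlations on all libraries were 0.0918 with PR and 0.111 with GR, with rank correlations of 0.211 and 0.0269. For JGE08 they were 0.0638 and 0.167, with rank correlations of 0.166 and 0.227. Of the 261 genes lowered by amifostine, 95 fell and 26 rose in ethanol JGT with dose (camera, adjusted p = 3.7e-07 with the preset correlation and adjusted p = 0.17 with an estimated correlation).

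A hypothesis is that genes of the licorice response respond in water as in ethanol. Genes that rose in ethanol GR had a median change of 0.126 log2 units in water GR, 89.4% of the 254 were higher, and the set test passed under both correlations. The hypothesis was formed from these same values, so they do not test it independently. Genes that rose in ethanol PR had a median of 0.0249 in water GR. The group that rose in ethanol GR had a median of 0.0454 in water PR (adjusted p = 0.000273 with an estimated correlation), so the response may not be specific to licorice, and position in the set, which goes with dose in both solvents, may add to it. For peony the same test gave an adjusted p of 0.472 with an estimated correlation in water PR, which leaves the question open, since a p that misses the threshold does not show that the genes do not respond.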
